A study of Mus musculus with 2 samples.

How the data were processed

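Nuclei of whole brain were profiled by droplet single-nucleus RNA sequencing in 2 libraries. A control library and a knockout library came from offspring aged 8 weeks, and both were labelled male. The series title places the ablated gene, Rest, in the placenta, so the brain itself was not the targeted tissue. Per the labels' protocols, nuclei were isolated with a commercial kit and libraries were made from the fresh nuclei with the 10x Genomics 3' chemistry. How many animals contributed to each library was not given in the sources used here.

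The deposited matrices hold UMI counts (unique molecular identifiers, each standing for a captured RNA molecule) per gene and nucleus, not normalized, over 32285 features. Cell Ranger 6.1.2 is named in the file headers, whereas the submitters' processing notes name Cell Ranger 3.0.1 together with STAR, Seurat and the genome build GRCm39. Gene symbols and identifiers were taken as the authors deposited them, and no coordinates are given because the annotation used here for gene order is of another build. The matrices held called nuclei, and no barcode had fewer than 500 UMIs or 362 genes. Strand use in counting was not given in the sources used here. Counts of genes that overlap a gene on the opposite strand, such as Zfas1, Kcnq1ot1 and Xist, therefore carry some uncertainty. The same holds for genes with near-identical copies, such as those of ribosomal proteins.

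Nuclei with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs were kept. The mitochondrial limit removed 117 of 11920 control barcodes and 72 of 12224 knockout barcodes, while the UMI and gene limits removed 0. Doublets were scored with Scrublet in scanpy 1.11.5, and the highest 8% of scores in each library were removed, which took out 944 and 972 nuclei. Scrublet's automatic threshold called 975 control nuclei (8.18%) and 0 knockout nuclei, so it had not worked in the knockout library and was used only as an alternative. After these steps 10859 control and 11180 knockout nuclei remained.

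Both libraries were clustered together without integration. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 20 neighbours was partitioned with leidenalg 0.10.2 at resolution 1.0. Clusters were named from markers of 26 cell types fixed before the data were examined. A name therefore means that the nuclei resemble that type by these markers, and no annotation by the authors was used. Of 30 clusters, 26 received a name and 4 stayed unnamed (clusters 3, 6, 8 and 19). Cluster 8 was left unnamed because its leading genes Meis2 and Tshz1 went against the neuroblast markers that scored highest. Cluster 6 had a median of 682 UMIs per nucleus and was led by Prl, Col1a1, Gh, Col1a2 and Pmch, genes of unrelated cell types. It was kept in the shares but left out of the comparisons within classes. That exclusion was decided after the data were seen, and it concerned 842 control nuclei (7.75%) and 327 knockout nuclei (2.92%).

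Within each class UMIs were summed per library and expressed as CPM, the count scaled to a common total, within the class. The log2 ratio of knockout over control was computed with a prior count of 0.5 and given with an exact conditional binomial 95% interval. Genes needed 200 summed UMIs in a class, and classes needed 200 nuclei in each library, which left 7 classes. Shares of nuclei carry exact Clopper-Pearson 95% intervals. With 1 library per group there was no replicate check and no test. All intervals cover counting error only and not variation between animals or between preparations, and no p-value or number of changed genes is given.

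There were 37 gene lists fixed before the data were examined. For each list with at least 5 measured members the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins. Its percentile describes these libraries and is not a test of the conditions. The genes named in each class were the 6 highest and 6 lowest log2 ratios among genes whose interval excluded 0 and whose CPM in the class was at least 0.2 of its highest CPM in any compared class. Mitochondrially encoded, ribosomal protein, haemoglobin and sex chromosome dosage genes and unnamed gene models were left out of the naming. Among genes measured in at least 5 compared classes and moved the same way in each, the 8 highest and 8 lowest medians were named. Members named for a list were taken from the 3 with the largest absolute log2 ratio, and lists given in brief name fewer or none. Rest and the sex chromosome genes were always named. A gene that these rules select is not reported here. These rules were also set before the data were examined.

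The calculation was tested on simulated counts drawn from the real means and class totals, with 200 genes changed by known folds. The simulated counts held counting (Poisson) error only, as the intervals assume. Recovery therefore checks the calculation and not the variation between nuclei, animals or preparations. In cerebellar granule neurons 95.7% of the unchanged genes lay within their interval among 9266 genes, and 95.3% of genes changed 1.5-fold were recovered in the right direction. In cluster 8, with the fewest UMIs but for microglia, the recovered share of genes changed 1.5-fold was 86.9% among 2404 genes.

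Alternatives covered the doublet rule, the UMI and mitochondrial limits, the clustering resolution, standardization within each library, TMM factors, totals without abundant transcripts, equal weight per nucleus, subtraction of a pooled background profile, thinning, the UMI minimum per gene and the prior count. Thinning to 1000 UMIs left out 1365 control nuclei (12.6%) and 962 knockout nuclei (8.60%). Other alternatives were added after the data were seen. They held the clusters of a class at the control library's proportions, restricted lists to members well expressed in the class, changed the denominator of the shares, took in smaller classes, and matched random lists also on each gene's level in cluster 6. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.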

Results

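Offspring of pregnancies with ablation of placental Rest, which encodes a repressor of neuronal genes in non-neuronal cells, were compared with control offspring at 8 weeks of age. The question was whether loss of this factor from the placenta leaves a trace in the cell types and gene expression of the adult brain. There was 1 control library and 1 knockout library of whole-brain nuclei, so every difference below is between these libraries and lacks a replicate check. The deposited matrices held 48472462 UMIs in 11920 control nuclei and 44415109 UMIs in 12224 knockout nuclei. After filtering, the median depth was 2146 UMIs and 1438 genes per control nucleus, and 1802.5 UMIs and 1272 genes per knockout nucleus. Mitochondrially encoded genes took 0.568% of the control UMIs and 0.523% of the knockout UMIs, and the nuclear transcript Malat1 took 7.50% in both.

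Rest was read at 17.4 CPM in the control library (95% interval 16.1 to 18.7, 730 UMIs) and at 15.8 CPM in the knockout library (14.6 to 17.1, 602 UMIs). Since the ablation was placental, this level does not check the label. Xist, the RNA that silences an X chromosome in female cells, stood at 2353 CPM in the control and 2432 CPM in the knockout library, although both were labelled male. It was detected in 9795 of 10859 control nuclei (90.2%) and in 10290 of 11180 knockout nuclei (92.0%). Among nuclei with at least 5000 UMIs these shares were 99.4% (99.1 to 99.7) and 99.4% (99.0 to 99.7). The Y-linked genes were near 0 in both libraries, with 1 and 1 UMIs for Ddx3y, 10 and 10 for Uty, 9 and 4 for Kdm5d, and 5 and 0 for Eif2s3y in control and knockout. The 0 UMIs of Eif2s3y allow up to 0.0969 CPM by the exact interval. In both libraries the values of Xist and of the Y-linked genes argue against the male label.

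The knockout library held a far larger share of cerebellar neurons and smaller shares of deep forebrain and brainstem neurons. Nuclei resembling cerebellar granule neurons, the small excitatory cells of the cerebellar cortex, made up 50.9% of the knockout nuclei (49.9 to 51.8) and 23.3% of the control nuclei (22.5 to 24.1), a 2.18-fold difference. The other cerebellar neurons stood higher by similar folds. Molecular layer interneurons were at 2.84% (2.54 to 3.17) against 1.29% (1.09 to 1.52), and Purkinje neurons at 0.564% (0.433 to 0.720) against 0.304% (0.209 to 0.427). Excitatory neurons of the diencephalon, midbrain or hindbrain were 15.3-fold lower, at 0.170% (0.102 to 0.265) against 2.61% (2.31 to 2.92).

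Medium spiny neurons, the principal neurons of the striatum, made up 1.62% (1.39 to 1.87) of the knockout and 4.52% (4.14 to 4.93) of the control nuclei. Oligodendrocytes, the myelinating glia, stood at 8.33% (7.82 to 8.85) against 14.3% (13.6 to 15.0), and their precursors at 1.23% (1.04 to 1.46) against 2.23% (1.96 to 2.52). The unnamed neuronal cluster 3, led by Rmst, Baiap3 and the vesicular glutamate transporter gene Slc17a6, was at 7.44% (6.96 to 7.94) against 13.5% (12.8 to 14.1). Cluster 8, led by Dlx1, Meis2 and Tshz1, was at 1.84% (1.60 to 2.11) against 4.89% (4.49 to 5.31). Pituitary cells numbered 3 in the knockout and 46 in the control library (0.0268%, 0.00553 to 0.0784, against 0.424%, 0.310 to 0.565). Shares that differed less were those of astrocytes (6.97% against 7.61%), cortical and hippocampal excitatory neurons (6.60% against 7.13%), GABAergic interneurons (1.31% against 1.25%), endothelial cells (1.15% against 1.20%) and vascular leptomeningeal cells (1.17% against 1.35%). Microglia or macrophages were at 1.86% (1.62 to 2.13) against 2.52% (2.24 to 2.84).

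Because granule neurons were so numerous, shares were also taken over nuclei outside the cerebellar neuron classes, a choice made after the data were seen. Over these 8153 control and 5113 knockout nuclei, oligodendrocytes were at 18.2% (17.2 to 19.3) in the knockout library, 0.957 times their control share. Microglia turned from lower to higher, at 4.07% (3.54 to 4.65) in the knockout against 3.36% (2.98 to 3.78). Astrocytes were then at 15.2% (14.3 to 16.3) against 10.1% (9.48 to 10.8), and cortical and hippocampal excitatory neurons at 14.4% (13.5 to 15.4) against 9.49% (8.87 to 10.2). Medium spiny neurons stayed lower, at 3.54% (3.05 to 4.08) against 6.02% (5.52 to 6.56), as did diencephalic, midbrain or hindbrain excitatory neurons, at 0.372% (0.224 to 0.580) against 3.47% (3.08 to 3.89).

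**Figure D1:**
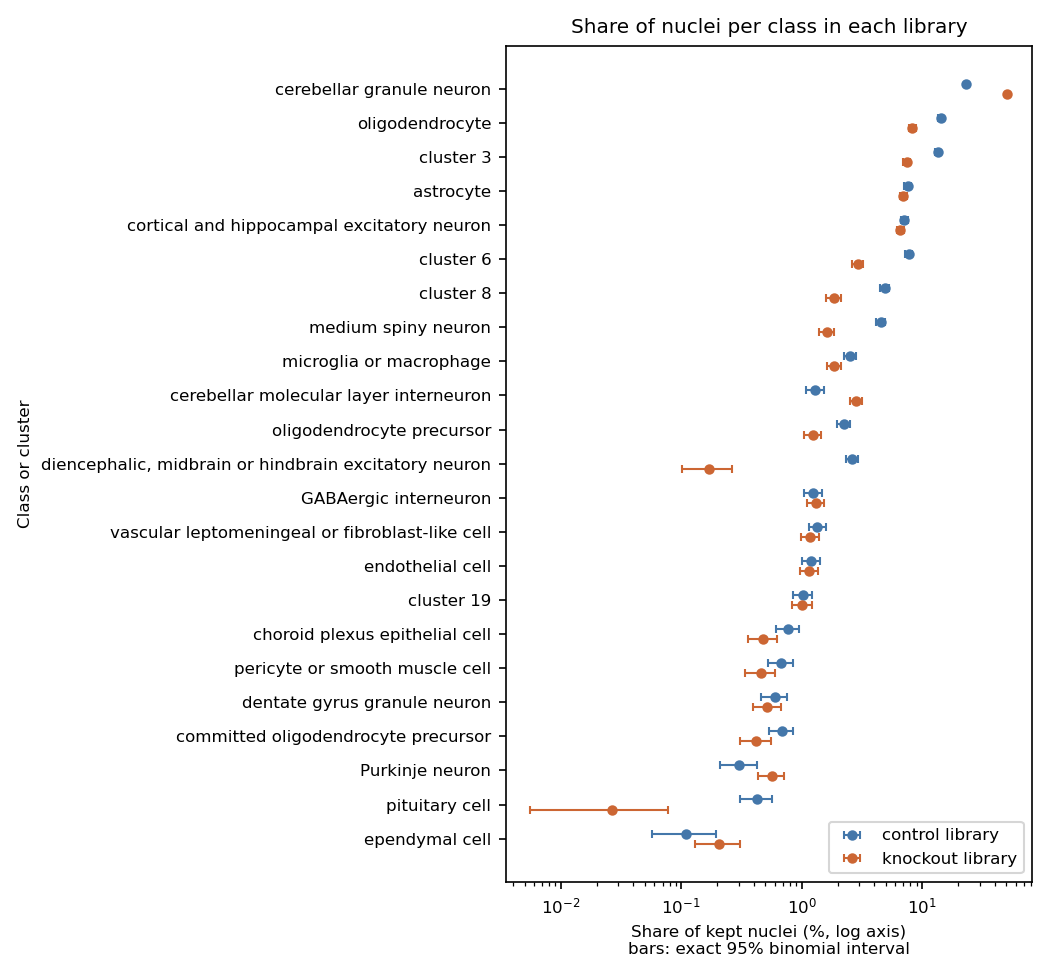
Share of kept nuclei in each class or unnamed cluster (horizontal logarithmic axis, percent) for the control library (blue) and the knockout library (orange), with bars for the exact 95% binomial interval, which covers counting error only. The granule neuron points lie at 23.3% and 50.9%, and the diencephalic, midbrain or hindbrain excitatory neuron points at 2.61% and 0.170%.

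In cerebellar granule neurons the metabolic and protein-folding genes measured in the knockout library stood below those of the control. Of the 73 measured genes of nuclear-encoded oxidative phosphorylation, 10 were higher and 63 lower, with a median log2 ratio of -0.18, below all 10000 random lists. Cox6b1 (-0.62) and Cox5a (-0.54), subunits of cytochrome c oxidase, and Uqcrfs1 (-0.51), a subunit of the bc1 complex, moved furthest. Of 18 glycolysis genes 2 were higher, with a median of -0.13 at percentile 0.11, led by Pgk1 (-0.44), Aldoa (-0.36) and Pgam1 (-0.35). Heat shock genes, which encode chaperones, had 2 of 18 members higher and a median of -0.28, below all random lists, with Hsph1 at -0.89, Hsp90aa1 at -0.42 and Hspa8 at -0.39. The mitochondrially encoded genes went the other way, with 11 of 12 higher and a median of 0.15 at percentile 99.1, led by mt-Nd5 (0.36), mt-Atp8 (0.21) and mt-Co1 (0.21). Set against random lists matched also on the level in the low-UMI cluster 6, oxidative phosphorylation moved to percentile 15.4, glycolysis to 48.5 and heat shock to 2.25.

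Among single genes in granule neurons, Rec8, a meiotic cohesin subunit, was at 43.4 CPM in the knockout and 15.8 CPM in the control library (log2 ratio 1.45, 1.08 to 1.86). Also higher were the mismatch repair gene Mlh1 (1.08, but 0.65 after thinning), Tgfbr3l (1.05), the collagen gene Col7a1 (1.02), Nbeal2 (1.01) and Phldb2 (0.98). The pituitary hormone genes Gh (-4.63, -5.14 to -4.19) and Prl (-4.31, -4.62 to -4.01) were lowest, in a class that does not make these hormones. Lower too were Ppp1r1b (-1.58) and Scn4b (-1.54), genes known for high expression in striatal neurons, and Rnf121 (-1.46). The dopamine system list had 1 of 7 measured members higher and a median of -0.99, with Ppp1r1b and Rgs9 (-1.23) among the furthest. Neuropeptide genes had a median of -0.45 with 1 of 9 higher, led by Penk (-1.26), Tac1 (-0.89) and Vgf (-0.76), and a median of -0.73 with at least 50 summed UMIs per gene. Ppp1r1b, Scn4b, Rgs9, Penk and Tac1 were among the 10 leading genes of medium spiny neurons, whose share was 0.358-fold in the knockout library. Neuronal genes with RE1 elements, the binding sites of the REST protein, had a median of -0.06 with 11 of 27 higher (percentile 0.765), led by Tubb3 (-0.95), Nefm (-0.78) and Vgf. Their median was 0.00 after thinning, at percentile 25.8. Synaptic vesicle and release genes had a median of -0.09 with 12 of 34 higher, below all random lists, led by Cplx1 (-0.61), Vamp1 (-0.61) and Stx1a (-0.49). Myelin genes had a median of -0.30 with 1 of 16 higher, also below all random lists, led by Ermn (-0.60), Mobp (-0.51) and Mal (-0.50). The share of oligodendrocytes was 0.583-fold in the knockout library. Whether free RNA of medium spiny neurons or oligodendrocytes lowered such genes in granule neurons or other classes was not tested on its own. Glucocorticoid responsive genes had 1 of 12 higher and a median of -0.18 at percentile 0.70, with Per1 at -0.49, Tsc22d3 at -0.47 and Nfkbia at 0.41 (-0.00 to 0.85). Against lists matched also on cluster 6, the RE1 list lay at percentile 20.4, synaptic vesicle genes at 4.47, myelin genes at 10.9, neuropeptide genes at 3.44 and glucocorticoid responsive genes at 2.78. Astrocyte transport and metabolism genes were higher, with a median of 0.11, 12 of 19 higher and percentile 97.9, led by Aqp4 (0.64), Gja1 (0.42) and Glul (-0.40).

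In cortical and hippocampal excitatory neurons, the immediate early genes, which neurons switch on within minutes of activity, stood higher while mitochondrially encoded and synaptic vesicle genes stood lower. Of 17 measured immediate early genes 11 were higher, with a median of 0.30 above all random lists, led by Ier2 (0.93), Arc (0.76) and Npas4 (0.54). All 12 mitochondrially encoded genes were lower, with a median of -0.40 below all random lists, led by mt-Cytb (-0.57), mt-Atp6 (-0.50) and mt-Co2 (-0.47). Of 34 synaptic vesicle and release genes 4 were higher, with a median of -0.14 below all random lists, led by Sv2c (-0.62), Rph3a (-0.44) and Syn1 (-0.41). Oxidative phosphorylation genes had a median of -0.07 with 18 of 73 higher, with Uqcrq at -0.36, Cox5a at -0.34 and Atp5e at -0.33. Glycolysis genes had a median of -0.09 with 3 of 18 higher, led by Pgam1 (-0.34), Pkm (-0.25) and Ldhb (-0.21). Heat shock genes had a median of -0.10 with 3 of 17 higher, led by Hsp90aa1 (-0.41), Stip1 (-0.36) and Hspd1 (-0.29). Against lists matched also on cluster 6 these last 3 lists lay at percentiles 92.3, 19.3 and 29.4, within the range of random lists.

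Bet1, a SNARE protein gene of transport from the endoplasmic reticulum to the Golgi, was at 43.2 CPM in the knockout and 12.8 CPM in the control library in these neurons (1.75, 1.41 to 2.11). Higher as well were the fibronectin gene Fn1 (1.65, but 0.72 after thinning), Ppm1m (1.44), the neuropeptide gene Cartpt (1.29, but 0.24 with equal weight per nucleus), the relaxin receptor gene Rxfp1 (1.15) and Ier2. Snca, which encodes alpha-synuclein, was lower (-1.28, -1.46 to -1.10), as were Prl (-4.15), Abi3bp (-1.39), Slc7a5 (-1.08) and Vangl2 (-0.95). Ccser1 read -1.09, but 0.20 after thinning. Calcium and CaMK signalling genes had a median of -0.12 with 7 of 29 higher (percentile 0.03), led by Calm3 (-0.54), Nrgn (-0.44) and Ryr1 (0.38). After thinning their median was -0.053 at percentile 17.6. Myelin genes had 0 of 10 higher and a median of -0.29 at percentile 0.01, led by Mobp (-0.64), Mal (-0.61) and Mog (-0.45). Astrocyte transport and metabolism genes had 11 of 15 higher and a median of 0.13 at percentile 99.2, led by Aqp4 (0.64), Slc1a3 (0.51) and Slc6a1 (0.43), but -0.048 after thinning.

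Cluster 3, the large unnamed neuronal cluster, also had higher immediate early genes and, in addition, higher lipid synthesis and ionotropic glutamate receptor genes. Of 12 immediate early genes 11 were higher, with a median of 0.37 above all random lists, and Arc at 0.85, Egr3 at 0.83 and Nr4a2 at -0.72. Cholesterol and fatty acid synthesis genes had 18 of 21 higher and a median of 0.12 at percentile 99.96 (0.21 after thinning). Hmgcs1 (-0.56) went against that median, Ldlr (0.42) and Fdps (0.20) with it. The AMPA, kainate and NMDA receptor genes had 12 of 17 higher and a median of 0.13 above all random lists, led by Grin2c (0.68), Grik3 (0.30) and Grin2d (-0.23). Grin2c was also among the 10 leading genes of cluster 1, a cluster of cerebellar granule neurons. Metabotropic glutamate receptor genes had the same median of 0.13 with 5 of 7 higher, just within the range of random lists. Patterning genes of the diencephalon, midbrain and hindbrain were lower, with a median of -0.20, 4 of 11 higher and percentile 0.21, led by Tcf7l2 (-1.10), Gata3 (-0.75) and Pou4f1 (-0.73). Oxidative phosphorylation (-0.08, 20 of 73 higher), glycolysis (-0.11, 5 of 18) and heat shock genes (-0.15, 2 of 17) were lower. Against lists matched also on cluster 6 they lay at percentiles 34.1, 6.1 and 0.32. Their furthest members were Uqcrq (-0.28), Ndufa5 (-0.27) and Ndufv2 (-0.27), Slc2a1 (-0.27, -0.64 to 0.09), Gapdh (-0.26) and Pfkl (-0.25), and Hsph1 (-0.31), Hsp90aa1 (-0.30) and Hspd1 (-0.27). Synaptic vesicle genes had a median of -0.09 with 7 of 34 higher, led by Erc2 (-0.28), Cplx1 (-0.27) and Vamp1 (-0.25). Myelin genes had a median of -0.18 with 4 of 13 higher (percentile 0.055).

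Within cluster 3, Tph2, which encodes the rate-limiting enzyme of serotonin synthesis in neurons, was at 1.05 CPM in the knockout and 21.9 CPM in the control library (-4.28, -5.71 to -3.31, but -2.90 without doublet removal and -3.28 after thinning). The metalloprotease gene Adamts15 was at 31.7 against 197 CPM (-2.64, -2.85 to -2.44). Gh (-3.92), Prl (-3.38), the axon guidance receptor gene Robo3 (-2.44) and Postn (-2.62, but -1.22 after thinning) were lower. Bet1 (1.64), the Purkinje cell gene Car8 (1.19, but 0.81 after thinning), Traip (0.99), Ecel1 (0.97), Palmd (0.93) and Gabrq (0.84), a GABA receptor subunit gene, were higher. After thinning Palmd read 1.52 and Gabrq 0.41. Cluster 3 mixes neurons of several kinds by its leading genes, and its makeup was not resolved further.

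Oligodendrocytes and astrocytes had higher mitochondrially encoded genes and lower oxidative phosphorylation, glycolysis and heat shock genes in the knockout library. In oligodendrocytes all 12 mitochondrially encoded genes were higher (median 0.39, above all random lists), led by mt-Atp8 (0.90), mt-Co1 (0.47) and mt-Nd4 (0.46), and 0.25 after thinning. In astrocytes all 11 were higher (median 0.35), led by mt-Nd5 (0.41), mt-Nd4l (0.40) and mt-Nd1 (0.39). Oxidative phosphorylation genes had medians of -0.13 in oligodendrocytes (15 of 66 higher) and -0.14 in astrocytes (18 of 59), both below all random lists. Their furthest members were Atp5k (-0.52), Cox5a (-0.47) and Ndufb7 (-0.46) in oligodendrocytes, and Uqcrq (-0.68), Sdhc (-0.55) and Ndufc1 (-0.47) in astrocytes. Glycolysis genes had medians of -0.22 (3 of 15 higher, led by Tpi1 at -0.64, Eno2 at -0.60 and Ldha at -0.53) and -0.14 (4 of 17 higher, with Hk2 at 1.78, Pfkp at -0.55 and Pgam1 at -0.50). Heat shock genes had a median of -0.22 in oligodendrocytes with 1 of 16 higher, led by Stip1 (-0.88), Hsph1 (-0.81) and Hspe1 (-0.40). In astrocytes their median was -0.18 with 3 of 12 higher, led by Hsph1 (-0.44), Hsp90aa1 (-0.44) and Hspa8 (-0.32), and -0.32 after thinning. Against lists matched also on cluster 6, these lists lay at percentiles 38.9, 23.2 and 1.29 in oligodendrocytes and 1.54, 9.93 and 12.6 in astrocytes, in the order just given.

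In oligodendrocytes cholesterol and fatty acid synthesis genes stood higher, with 18 of 21 members above 0 and a median of 0.17 at percentile 99.97, led by Cyp51 (0.45), Ldlr (0.41) and Idi1 (0.36). Myelin genes had 15 of 18 members higher and a median of 0.08 at percentile 94.2, within the range of random lists (-0.079 without doublet removal), with Opalin at 0.41, Mobp at -0.37 and Trf at 0.31. The cadherin gene Cdh2 was at 364 CPM in the knockout against 204 CPM in the control library (0.84, 0.68 to 0.99), followed by Zfas1 (0.75), the midbrain-hindbrain gene En2 (0.70), Snx29 (0.66), Sema4c (0.66) and Diras2 (0.65). Mylk, which encodes myosin light chain kinase, was at 19.1 against 98.0 CPM (-2.34, -2.87 to -1.88). Prl (-4.78), Gh (-4.11), Snca (-1.78), Pxdn (-1.38) and the clock-controlled gene Hlf (-1.27) were also lower. Circadian clock genes had 1 of 10 higher, a median of -0.16 at percentile 1.92, and Hlf, Per1 (-0.53) and Nr1d2 (-0.37) in front. Imprinted genes had a median of -0.16 with 5 of 18 higher (0.05 without doublet removal), led by Plagl1 (-1.05), Ndn (-0.74) and Meg3 (-0.53). The neuronal genes with RE1 elements had a median of -0.13 with 7 of 23 higher, led by Tubb3 (-1.03), Nefm (-0.79) and Vgf (-0.58), but 0.19 without doublet removal. Ionotropic glutamate receptor genes likewise read -0.26 with 3 of 11 higher, led by Grik1 (-0.81), Grin2b (-0.50) and Gria4 (0.37), 0.15 without doublet removal and -0.49 with the pooled profile subtracted. Against lists matched also on cluster 6 the imprinted, RE1 and receptor lists lay at percentiles 15.6, 88.3 and 6.95.

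In astrocytes Abi3bp (2.29, 1.79 to 2.85), the collagen genes Col1a1 (1.99, 1.70 to 2.31) and Col1a2 (1.63), Slco4a1 (1.69), the D-amino acid oxidase gene Dao (1.69) and Emid1 (1.55) were higher. Astrocyte nuclei came from clusters 7, 10, 18 and 22, with 464, 264, 67 and 31 control nuclei and 282, 222, 171 and 104 knockout nuclei. With these clusters held at the control proportions, a choice made after the data were seen, the values were 0.98 for Abi3bp, 1.23 for Col1a1, 0.81 for Col1a2, 0.34 for Slco4a1, 0.79 for Dao and 0.36 for Emid1. Lower were Prl (-4.60) and the neuronal genes Tubb3 (-1.31), Nefl (-1.02), Hpca (-0.98) and Cck (-0.96), as well as Nkiras1 (-0.94). Astrocyte transport and metabolism genes had a median of -0.06 with 7 of 23 higher (percentile 2.70), and Aqp4 at 0.39, Slc6a11 at -0.35 and Slc1a3 at 0.35. That median was 0.087 (percentile 78.0) with the clusters at the control proportions and -0.22 (percentile 0.05) without doublet removal. In cluster 3 the same list read 0.25 with 15 of 18 higher, led by Gja1 (0.78), Aqp4 (0.77) and Slc1a3 (0.64), and in oligodendrocytes 0.15 with 11 of 13 higher.

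In cluster 8 all 6 measured immediate early genes were higher, with a median of 0.39 at percentile 99.98, led by Nr4a1 (1.07, 0.70 to 1.45), Btg2 (0.46) and Npas4 (0.45). Zbtb18 (0.90), Dmtf1 (0.81), Me3 (0.78), Lrrtm3 (0.78) and the corticotropin releasing hormone receptor gene Crhr1 (0.77) were higher. The tubulin gene Tubb3 (-1.12, -1.55 to -0.73), Zfp131 (-0.99), Marcks (-0.98), Hmgcs1 (-0.97), Sdk2 (-0.86) and Skp1a (-0.85) were lower. After thinning Nr4a1 read 0.59, Dmtf1 0.34 and Sdk2 -1.46, and with equal weight per nucleus Hmgcs1 read -0.50. Oxidative phosphorylation genes had a median of -0.20 with 4 of 24 higher, and Atp5l at 0.49, Ndufa4 at -0.47 and Atp5f1 at -0.40, at percentile 9.65 when matched also on cluster 6. Voltage-gated potassium channel genes had 11 of 13 higher and a median of 0.18 at percentile 99.1, led by Kcnip2 (0.49), Kcna4 (0.31, -0.01 to 0.61) and Kcnc3 (0.30, -0.10 to 0.68).

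Microglia or macrophages, the immune cells of the brain, had 460 measured genes and the lowest depth of the compared classes. Their nuclei came from cluster 13 (248 control, 167 knockout) and cluster 28 (26 control, 41 knockout), which was led by Cd74, Stab1, Lyz2 and Mrc1, so the class made up of both differed in makeup between the libraries. Their mitochondrially encoded genes were higher (6 of 7, median 0.29, percentile 99.6), led by mt-Co1 (0.53), mt-Nd2 (0.37) and mt-Co3 (0.33). That median was 0.10 without doublet removal. Disease-associated microglia genes had a median of 0.24 with 4 of 5 higher (percentile 99.7), with Cd9 at -0.43, the lipoprotein gene Apoe at 0.43 and Ctsb at 0.26 (-0.02 to 0.53). The median of the disease-associated microglia genes in microglia or macrophages was 0.23 with the 2 clusters at the control proportions. Without doublet removal their median was 0.0070 at percentile 85.4, within the range of random lists. Homeostatic microglia genes had a median of -0.11 with 3 of 13 higher, within the range of random lists (percentile 4.56), led by P2ry13 (-0.50), Sall1 (-0.37) and Olfml3 (-0.35). The genes ranking highest were Csmd3 (0.72), Atp1a1 (0.64), Scn2a (0.63), Kcnq1ot1 (0.62), Gramd1a (0.61) and Slc1a3 (0.61), and the lowest Zwint (-0.92), Fchsd2 (-0.68), Scoc (-0.66), Snap25 (-0.64), Pkm (-0.56) and Calm3 (-0.52). Several of these are neuronal or astrocytic genes, and without doublet removal Kcnq1ot1 read 0.07, Slc1a3 0.22, Csmd3 0.33, Zwint -0.42 and Snap25 -0.16.

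**Figure D2:**
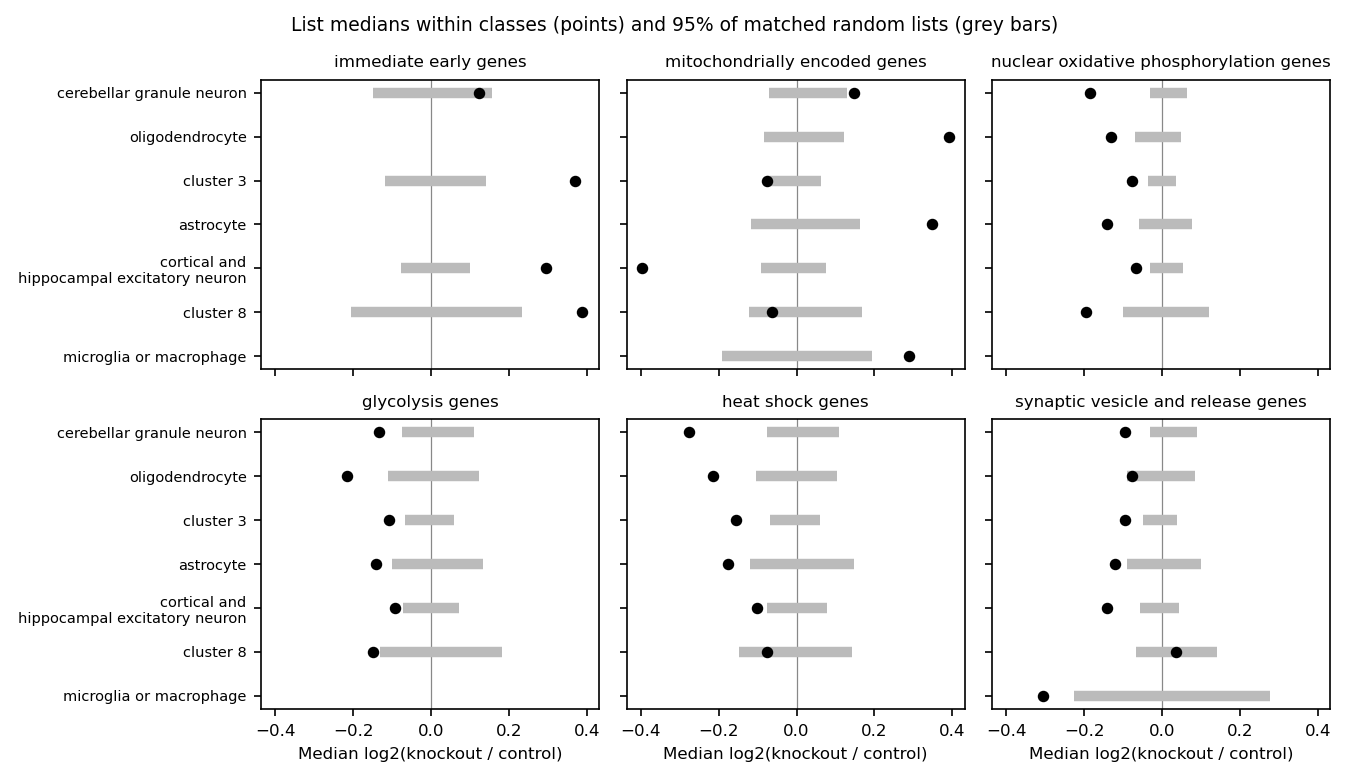
Median log2 ratio of knockout over control (horizontal axis) for 6 gene lists in the 7 compared classes; points are the lists, grey bars hold 95% of 10000 random lists matched on mean expression, and a class with fewer than 5 measured members has no point. Immediate early genes lie at 0.37 in cluster 3 and 0.30 in cortical and hippocampal excitatory neurons, and mitochondrially encoded genes at 0.39 in oligodendrocytes and -0.40 in cortical and hippocampal excitatory neurons.

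The genes that encode REST and its co-repressors did not stand apart in any compared class with enough measured members. Their median was 0.04 in granule neurons (9 of 15 higher), 0.00 in cluster 3 (8 of 15), 0.06 in cortical and hippocampal excitatory neurons (10 of 14, but -0.057 after thinning) and 0.01 in oligodendrocytes (7 of 11), with percentiles from 42.5 to 87.7 over the compared classes. The furthest members were Cdyl (0.37), Hdac1 (0.34) and Ctdsp1 (0.25) in granule neurons. The RE1 list lay within the range of random lists in cluster 3 (-0.03, percentile 14.8), cortical and hippocampal excitatory neurons (-0.03, percentile 17.2), astrocytes (-0.09, percentile 4.07) and cluster 8 (0.11, percentile 92.4). It left that range under other settings in all but cluster 3. In astrocytes it was at -0.33 with well-expressed members, below all random lists, and at 0.26 (percentile 99.99) without doublet removal. It was also below the range there with at least 50 summed UMIs per gene, equal weight per nucleus, subtraction of the pooled profile or clusters at the control proportions. In cortical and hippocampal excitatory neurons it was at -0.11 (percentile 1.27) after thinning, and in cluster 8 it was above the range with equal weight per nucleus and, at percentile 99.6, when matched also on cluster 6.

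Some genes moved the same way in each compared class where they were measured, among 3922 genes measured in at least 5 classes. Highest by median were the granule neuron genes Cbln3 (1.54), Gabra6 (1.21) and Cbln1 (1.08), followed by Grm4 (0.54), Tspan9 (0.48), Adcy1 (0.47), Sipa1l3 (0.45) and Plpp3 (0.45). In granule neurons themselves Cbln3 stood at 0.28, Gabra6 at 0.16 and Cbln1 at 0.36. Lowest were Prl (-4.31), the thalamic transcription factor gene Tcf7l2 (-1.10), Tubb3 (-0.99), the neuronal calcium sensor gene Hpca (-0.91), Rnf121 (-0.82), Elavl2 (-0.81), Zfp131 (-0.65) and Ip6k2 (-0.59).

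Over the whole library, where levels and composition mix, monoamine genes were lower in the knockout. Dopamine system genes had 1 of 14 higher and a median of -1.03, led by the transporter genes Slc6a3 (-1.66) and Slc18a2 (-1.65). Serotonin system genes had 1 of 13 higher and a median of -0.56, led by the serotonin transporter gene Slc6a4 (-4.18, -5.21 to -3.41), Tph2 (-3.00) and Htr1d (-1.15). With classes held at the control library's shares these medians were -0.47 and -0.29. Immediate early genes had 16 of 20 higher and a median of 0.31, led by Ier2 (0.80), Dusp1 (0.58) and Arc (0.57). Reactive astrocyte genes had 6 of 9 higher and a median of 0.27, led by Cd44 (1.08), Gfap (0.70) and Vim (0.69). This list was not recomputed at the control library's shares, so composition may enter its median. Astrocyte clusters 22, led by Aqp4 and Gfap, and 18 were 3.26-fold and 2.48-fold in share in the knockout library. Astrocyte clusters 7 and 10 were 0.590-fold and 0.817-fold. Myelin genes had a median of -0.21 with 2 of 18 higher, but 0.03 at the control library's shares. Patterning genes were lower for the diencephalon, midbrain and hindbrain (-0.46, 3 of 15 higher, led by Lef1 at -1.83, Tcf7l2 at -1.57 and En2 at 1.18) and within the random range for the forebrain (0.07, 7 of 11). Ribosomal protein genes had 64 of 81 higher and a median of 0.10, and astrocyte transport and metabolism genes 15 of 23 higher and a median of 0.13. Neuropeptide genes (-0.33, 5 of 21 higher), voltage-gated potassium channel genes (-0.19, 11 of 28), metabotropic glutamate receptor genes (-0.19, 2 of 7), axon guidance genes (-0.14, 14 of 40), imprinted genes (-0.13, 10 of 33) and synaptic adhesion genes (-0.07, 18 of 48) were lower than at least 97.5% of random lists. At the control library's shares, the medians were -0.086 for neuropeptide genes and -0.014 for imprinted genes, the latter within the range of random lists (percentile 15.6). Within the range of random lists were citric acid cycle genes (-0.00, 10 of 21 higher), GABA receptor genes (-0.08, 5 of 15), voltage-gated sodium and calcium channel genes (-0.06, 12 of 29), insulin and growth factor receptor genes (0.02, 16 of 29), nuclear long noncoding RNA genes (-0.06, 4 of 10) and genes known to differ between mouse strains (-0.08, 1 of 7).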

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

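The tests of brain regions, of granule neurons alone, of the filters, of cytoplasmic RNA, of granule neuron markers, of shared genes and of chromosomal windows were chosen after their results were seen, and matching on the low-UMI cluster 6 after the list medians but before its own result. Mitochondrially encoded genes were higher in the knockout library in oligodendrocytes (median log2 ratio 0.39), astrocytes (0.35), microglia or macrophages (0.29) and granule neurons (0.15) and lower in cortical and hippocampal excitatory neurons (-0.40). The value was 0.25 in oligodendrocytes after thinning and 0.10 in microglia without doublet removal. These opposite directions drew attention, and the difference between the classes was not tested. AMPA, kainate and NMDA receptor genes went opposite ways in cluster 3 (0.13) and oligodendrocytes (-0.26), and this difference was not tested either. In oligodendrocytes they read 0.15, the same direction as in cluster 3, without doublet removal, and lay within the random range (percentile 6.95) when matched also on cluster 6.

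Cerebellar granule neurons were a 2.18-fold larger share of the knockout library. An excess of granule neurons alone is argued against, because their fold divided by that of molecular layer interneurons and Purkinje neurons together was 1.02 (0.847 to 1.23). Removal of doublets is argued against as well, since the fold was at least 2.24 without it. With 1000 UMIs the fold was also at least 2.24. That setting only removes more nuclei, and the UMI and gene limits had removed 0, so an effect of lost low-UMI nuclei could not be tested. Different proportions of brain regions in the homogenates remain a candidate explanation, as the other cerebellar neurons together were 2.14-fold higher (1.79 to 2.56). A larger cerebellum in the knockout offspring would give the same values for the cerebellar neurons and was not tested, since each group had 1 library. By itself it would not change the proportions among neuron classes of other regions, which also differed. Over nuclei outside the cerebellar neuron classes, diencephalic, midbrain or hindbrain excitatory neurons were 0.107-fold and medium spiny neurons 0.588-fold. Cortical and hippocampal excitatory neurons were 1.52-fold and oligodendrocytes 0.957-fold. These nuclei still include any glia and vessel cells of the cerebellum, so a larger cerebellum could change the shares taken over them.

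Oxidative phosphorylation, glycolysis and heat shock genes were lower in most classes. Less cytoplasmic RNA on the nuclei should lower mitochondrially encoded and ribosomal protein genes alike. In oligodendrocytes and astrocytes mitochondrially encoded genes were above the random range (lowest median 0.35) and ribosomal protein genes were not below 0, which goes against it. The rule for this call was set after these medians were seen, so it is not an independent test. In oligodendrocytes it rests on mitochondrially encoded genes alone, as ribosomal protein genes lay within the random range (0.032, percentile 91.4). Less cytoplasmic RNA and lower expression in the knockout brains cannot be told apart for granule neurons and for cortical and hippocampal excitatory neurons, where these lists went opposite ways. In the former mitochondrially encoded genes were at 0.15 and ribosomal protein genes at -0.030 (percentile 1.47, but 100 when matched also on cluster 6). In the latter they were at -0.40 and 0.062. They cannot be told apart for cluster 3 either, where mitochondrially encoded genes lay within the random range (-0.075, percentile 2.77) and ribosomal protein genes at 0.055, but at 0.015 and within that range after thinning. Less free RNA of the kind held by cluster 6 may contribute, since 4 of the 17 pairs of class and list below the range of random lists stayed below it after matching on cluster 6. However, the level in cluster 6 was summed over both libraries, with 842 control and 327 knockout nuclei. A gene lower in the knockout library can therefore rank as higher in cluster 6. The matching may thus remove part of the library difference itself, and the lost pairs are not independent evidence for free RNA. As some pairs stayed and most did not, this source and lower expression in the knockout brains cannot be told apart.

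Some genes were higher, and others lower, in each class where they were measured. Free RNA of granule neurons is a candidate source for the granule neuron markers, of which 9 of 10 were higher over the other compared classes than in granule neurons (medians 0.62 and 0.28). Free RNA alone should move a gene least where its own expression is highest. Genes highest in a compared class were chosen for moving the same way in each other class in one random part of the UMIs, and measured in the remaining UMIs. Their mean log2 ratio in the class with the highest level was 0.653 (0.452 to 0.831) of that over the other classes, and 0.457 (0.302 to 0.656) for those with a median of at least 0.3 in absolute log2 ratio. Bounds of 0.5, below which values were taken as free RNA alone, and 0.75, above which they were taken as without it, were set after the result was seen. They were not derived from a model of free RNA. Both intervals cross at least 1 of these bounds, so free RNA and other sources cannot be told apart for these genes. Genes highest in a class that was not compared, such as Prl in pituitary cells, were outside this test. The share of pituitary cells was 0.0633-fold in the knockout library, and free RNA of these cells was not tested as a source of Prl. Chance adds genes too, as 67.7 of the 374 genes higher in each class and 110 of the 456 lower would be expected if classes were independent. A chromosomal segment that differs between the animals could act on such genes in all classes, and 4 versions of a search for neighbouring genes were run. Between 0% and 22.3% of shuffles held as dense a window, with 2 versions under 5%, so a segment and the group cannot be told apart. These 2 versions found overlapping windows on chromosome 7, with 11 such genes (0% of shuffles) and 9 (4.6%). Calm3 lay in both windows and Apoe in the first, so this limit also holds for their values in single classes. The search counted only genes moved the same way in each class measured, with an absolute median of at least 0.3 or 0.5. A segment is therefore not excluded for other named genes.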

How the results depend on the processing

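Other denominators, restricted lists, clusters held at the control proportions and matching on cluster 6 were chosen after the data were seen, and the remaining alternatives before. No paired analysis was possible because each group had 1 library and the labels share no replicate numbers. Over all alternatives, 101 of 114 shares and 1072 of 1136 list medians moved by less than their interval and were not counted as reversed. The same held for 594 of 636 values of single genes and 108 of 112 of shared genes. Counted as reversed were 1, 9, 1 and 0. For list medians the interval had the width of the random range. Shares counted as reversed only if their interval excluded 1, and list medians only if outside the random range at first. Other changes of direction were left out of these reversals. They include the shares of astrocytes and cortical and hippocampal excitatory neurons outside the cerebellar classes, and the RE1 list in astrocytes without doublet removal. Among 110 percentiles matched also on cluster 6, 76 kept their place, which includes lists that lay within the random range before and after. Of the rest, 29 came to lie within that range, 4 came to lie outside it and 1 was reversed. Causes were not tested unless given. The fold of the granule neuron share was 2.08 with Scrublet's automatic threshold, which called 0 knockout nuclei, and 2.07 without cluster 6. The oligodendrocyte share was 0.529-fold with at most 1% mitochondrial UMIs. Over nuclei outside the cerebellar classes the folds were 0.957 for oligodendrocytes, 0.908 for cluster 3, 0.588 for medium spiny neurons, 0.107 for diencephalic, midbrain or hindbrain excitatory neurons and, reversed, 1.21 for microglia, since the larger granule share no longer enters the denominator. Without doublet removal, medians reversed for the RE1 list (0.19), ionotropic glutamate receptor genes (0.15) and imprinted genes (0.054) in oligodendrocytes, for synaptic vesicle (0.20) and calcium signalling genes (0.016) in astrocytes, and for synaptic vesicle genes in microglia (0.20). The same setting gave 0.26 for the RE1 list in astrocytes, and for mitochondrially encoded genes 0.27 in oligodendrocytes and 0.10 in microglia. Thinning to 1000 UMIs gave 0.0018 for the RE1 list in granule neurons (reversed) and -0.11 in cortical and hippocampal excitatory neurons. In the latter it reversed astrocyte transport genes (-0.048) and Ccser1 (0.20). It gave 0.25 for mitochondrially encoded genes in oligodendrocytes, -0.12 for oxidative phosphorylation in cluster 3 and -0.32 for heat shock genes in astrocytes. Equal weight per nucleus gave 0.25 for mitochondrially encoded genes in oligodendrocytes and 0.41 for immediate early genes in cortical and hippocampal excitatory neurons. Well-expressed members of the RE1 list gave -0.25 in oligodendrocytes and -0.33 in astrocytes, and subtraction of 10% of the pooled profile gave -0.24 in oligodendrocytes. With classes at the control library's shares, whole-library medians were -0.29 for serotonin genes, -0.47 for dopamine genes and 0.033 for myelin genes (reversed). After matching also on cluster 6, oxidative phosphorylation lay at percentile 15.4 in granule neurons, 38.9 in oligodendrocytes, 34.1 in cluster 3, 92.3 in cortical and hippocampal excitatory neurons and 9.65 in cluster 8. Glycolysis lay at 48.5, 23.2, 6.1, 19.3 and 32.4 in the same order and at 9.93 in astrocytes. Heat shock genes lay at 12.6 in astrocytes and 29.4 in cortical and hippocampal excitatory neurons. The RE1 list lay at 20.4 in granule neurons, 88.3 in oligodendrocytes and 99.6 in cluster 8, mitochondrially encoded genes at 97.5 in microglia, and ribosomal protein genes at 100 in granule neurons (reversed). Among the 7 compared classes depth limits microglia most, with 460 measured genes.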

Other observations

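The smaller classes, the single genes followed across classes and the correlation in this part were chosen after the data were seen. Immediate early genes lay within the range of random lists in granule neurons, the largest class (median 0.12, percentile 93.3). Of the classes with fewer than 200 nuclei in a library, medium spiny neurons and cluster 19 had higher immediate early genes. All 5 measured members were higher in medium spiny neurons (median 0.43), led by Nr4a1 (1.01), Npas4 (0.80) and Junb (0.43). In cluster 19, with a median of 15937 UMIs per nucleus and the highest median doublet score of the 30 clusters (0.202), all 6 were higher (median 0.98), with Btg2 at 1.16, Npas4 at 1.15 and Nr4a1 at 1.13. Medium spiny neurons also had more somatostatin RNA (Sst, 140 against 28.6 CPM, log2 ratio 2.29, 1.90 to 2.69) and Rreb1 (1.81), and less Id4 (-1.21) and Inhba (-1.13). Mitochondrially encoded genes were lower in medium spiny neurons (0 of 11 higher, median -0.47) and in GABAergic interneurons (0 of 9 higher, median -0.73). They were also lower in oligodendrocyte precursors (0 of 8 higher, median -0.27, percentile 0.1), vascular leptomeningeal or fibroblast-like cells (0 of 8, -0.35, percentile 1.07) and cluster 19 (1 of 11, -0.31, percentile 0.02), whereas they were higher in oligodendrocytes, astrocytes, microglia and granule neurons. The differences between these classes were not tested. Medium spiny neurons had 0 of 9 dopamine system genes higher (median -0.43, below all random lists), led by Drd2 (-0.63), Adcy5 (-0.58) and Pde10a (-0.53). Of 8 astrocyte transport and metabolism genes 7 were higher in them (median 0.40, percentile 99.98). In GABAergic interneurons the neuropeptide gene Npy (-0.98, -1.14 to -0.82) and the gene of the corticotropin releasing hormone binding protein Crhbp (-1.18) were lower and Cxcl14 (1.15) was higher. Endothelial cells had more Apoe RNA (1.23, 0.98 to 1.49), and with it more RNA of neuronal and glial genes such as Gpm6b (1.09), Cpe (0.85), Grin2b (0.79) and Slc17a7 (0.72), and less of the amino acid transporter gene Slc7a5 (-1.63, -2.06 to -1.23) and of Rgs5 (-1.15, -1.37 to -0.94), a pericyte gene.

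Snca, which encodes alpha-synuclein, was lower in each class where it was measured. It stood at -1.16 (-1.36 to -0.95) in granule neurons, -1.78 (-2.24 to -1.36) in oligodendrocytes, -1.29 (-1.55 to -1.03) in cluster 3, -1.28 (-1.46 to -1.10) in cortical and hippocampal excitatory neurons, -0.83 in medium spiny neurons and -0.83 in cluster 19. Adamts15 was also lower in each class where it was measured, from -3.33 (-3.61 to -3.07) in cerebellar molecular layer interneurons, where it stood at 135 against 1360 CPM, to -0.36 (-0.52 to -0.20) in GABAergic interneurons. In vascular leptomeningeal cells it was at -1.87, in cluster 3 at -2.64, in cluster 19 at -1.81 and in cortical and hippocampal excitatory neurons at -0.65. Bet1 was higher in cortical and hippocampal excitatory neurons (1.75), cluster 3 (1.64) and granule neurons (0.47, 0.10 to 0.86), and at 0.00 (-0.41 to 0.40) in oligodendrocytes. The haemoglobin genes Hbb-bs (3.75, 3.32 to 4.24) and Hba-a1 (4.64, 3.76 to 5.86) were far higher in cluster 19 of the knockout library, against 0.52 and 0.83 over the whole library.

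Across genes, which are not independent replicates, the log2 ratio tended to be lower the higher a gene's level in cluster 6 was relative to the class. That level was summed over both libraries, with 842 control and 327 knockout nuclei, so part of this relation may arise from the library difference itself. Spearman's rho was -0.493 in granule neurons, -0.317 in oligodendrocytes, -0.206 in cluster 3, -0.219 in astrocytes, -0.266 in cortical and hippocampal excitatory neurons, -0.341 in cluster 8 and -0.164 in microglia or macrophages.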
